A study of Mus musculus with 16 samples.

How the data were processed

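Messenger RNA levels were measured in 16 samples of mouse bone-marrow-derived macrophages on 1-channel Affymetrix arrays, with 1 biotin-labelled total RNA sample per array. Per the labels, the cells were wild type or NFAT5 knockout (KO) on a 129sv background, either unstimulated or stimulated with LPS, with 4 arrays in each of the 4 groups. The LPS dose and the length of stimulation are not given in the sources used here. Nothing in the labels says whether arrays of a group came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical. By the sex-linked transcripts described below, each KO group held male and female samples, so the spread in KO groups is not only technical.

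The deposited values are log2 expression levels summarised per probe set by robust multi-array average (RMA), per the submitters' processing notes, which name no version. RMA corrects background, normalises the arrays to a common distribution and combines probes, so a change shared by all genes would be removed and changes of dim genes are compressed towards 0. Array medians lay between 6.76 and 6.86. The number of arrays limits the precision. The file held 34760 probe sets. The platform annotation gave 1 gene for 21640 of them and several genes for 1321, and it did not list 11799, which are unnamed here. Symbols of 21553 probe sets were looked up by gene identifier in a RefSeq gene table of assembly GRCm38.p6, which changed 0 of them, and 87 had no entry there. That table was used for names and chromosomes only. Each of 19937 genes was represented by its brightest probe set over the 16 arrays. Of these genes, 954 had several probe sets.

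All 16 arrays entered one linear model with a mean per group (lmFit and eBayes of limma 3.58.1 in R 4.3.3), which left 12 residual degrees of freedom. The 5 contrasts were LPS against unstimulated in each genotype, KO against wild type in each treatment, and the difference between genotypes in the LPS response. P-values were adjusted over all genes by the Benjamini-Hochberg method, and an adjusted p under 0.05 made a call. Every adjusted p for a gene comes from this limma fit unless another setting is named. Genes responsive to LPS were those called for the average LPS effect of both genotypes with at least a 2-fold change. In this balanced design that average is independent of the genotype difference under LPS. For Nfat5, the single probe set was also compared by an exact two-sided permutation test.

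There were 29 gene lists, fixed before the data were examined. Each was tested in the 5 contrasts with camera at a preset correlation of 0.01, which compares the list with all other genes, and the 145 p-values were adjusted together. Camera with an estimated correlation and fry were run beside it. Of 69 calls with the preset correlation, 24 held with the estimated one. Fry, which asks whether members move one way on balance and compares them with no other genes, made 69 calls. Members measured and listed numbered 12 of 14 for the osmotic stress list, 27 of 32 for the interferon list, 12 of 14 for MHC class II, 16 of 21 for cholesterol synthesis, 8 of 13 for erythroid and megakaryocyte markers and 4 of 5 for the sex-linked genes.

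Named genes followed a rule fixed before the data were examined: per contrast, the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap (no condition on overlap for the difference in response), up to 4 members with the smallest p per list, called or not, and always Nfat5, Nos2, Il6, Tnf, Il1b, Il12b, Ccl2, Ptgs2 and Ciita. Some were left out for length. Predicted genes, clone names, small RNAs and tandem copies were not named. Exceptions are marked as chosen after their values were seen.

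The replicate numbers come from the sample titles. Deviations from the group means correlated between KO and wild-type arrays of the same number by 0.16 to 0.44 without LPS and by 0.19 to 0.52 with LPS. All lay above the minimum of 0.1 set for pairing, so the numbers paired the arrays in both genotype contrasts, and values with the number as a block are given where they change a call or move a count by more than 1.5 times. No arrays were duplicates of each other: the SD of the difference between arrays of a group ranged from 0.235 to 0.546.

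The procedure was tested on simulated data with the real spread and 19937 genes. For KO against wild type with LPS, it recovered 43.3% of genes changed by 0.5 on the log2 scale, 91% of those changed by 1 and 100% of those changed by 2, with 5 false calls among 19737 unchanged genes. For the difference in response the shares were 13.4%, 80.6% and 100%, with 6 false calls. For KO against wild type without LPS, simulated with no change at all, it called 0 of 19937. A list of 20 genes shifted by 0.5 was called and 0 of 50 unshifted lists were. The simulated noise was independent between genes, whereas the correlation within real lists was estimated at up to 0.64. The simulation therefore does not show how often lists of correlated genes are called falsely.

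The alternatives tried were the replicate block (fixed or random), only the groups of a contrast, filters on dim genes at the 30 and 50 percentiles of mean expression, the mean of all probe sets, cyclic loess or median centring on top of RMA, a trended robust variance, array weights, a 4-fold minimum, and leaving out each array in turn. Added after the data were seen were a term for sex, arrays with Xist above Kdm5d only, arrays numbered 1 to 3 only, no X and Y genes, 8 arrays with the block, and the fit without both unstimulated arrays numbered 1. By the sex-linked transcripts only the KO groups held both sexes, so the sex term rests on KO number 4 against KO numbers 1 to 3. Without the block it cannot be told apart from a difference of number 4. Coordinates and exons were not analysed here.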

Results

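Expression was compared across 16 arrays of bone-marrow-derived macrophages, immune cells grown from marrow precursors. NFAT5 is a transcription factor best known for switching on genes that protect cells from hypertonic stress, and LPS is a bacterial cell wall component sensed by Toll-like receptor 4. The design asks how LPS changes expression in wild-type and in NFAT5 KO cells, how the genotypes differ in each state, and whether the response to LPS depends on the genotype. The first principal component held 67.2% of the variance and the second 7.55%. On the second, the arrays numbered 4 scored -6.42 and -18.5 in wild-type and -24.4 and -31.4 in KO cells, without and with LPS. Of the others only wild-type unstimulated array 1 was negative (-7.99). Correlations between arrays ranged from 0.981 to 0.996 within a group and from 0.925 to 0.994 between groups.

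Nfat5 itself, on chromosome 8, was measured by 1 probe set. Without LPS its level was 9.39 ± 0.21 in wild-type cells and 9.04 ± 0.12 in KO cells (SD, n = 4), and an exact two-sided permutation test gave p = 0.0571. With LPS the levels were 10.07 ± 0.34 and 9.09 ± 0.29, a log2 difference of -0.98 (1.97-fold), with p = 0.0286 in the same exact test, the smallest it can give. Nfat5 rose by 0.68 ± 0.162 (SE) with LPS in wild-type cells (limma adjusted p = 0.003), and in KO cells the change was 0.05 ± 0.162 (adjusted p = 0.889). Which exons the altered allele lacks is not given in the sources used here, so a signal in KO arrays does not check the labels.

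The genotypes also differed in sex-linked transcripts. Xist, made from the inactive X of female cells, lay between 11.7 and 12.5 in 10 arrays: all 8 wild-type arrays and the KO arrays numbered 4 in both treatments. In the other 6, the KO arrays numbered 1 to 3, it lay between 5.67 and 6.29, and the Y-linked Kdm5d lay between 7.36 and 8.46, against at most 5.53 in the 10. Uty and Eif2s3y separated the arrays in the same way. By these transcripts, 6 of the 8 KO samples were male and all other samples female, so genotype and sex largely coincide in the genotype comparisons.

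LPS raised inflammatory mediators in wild-type macrophages. Il6 rose 276-fold, by 8.11 ± 0.136 on the log2 scale (SE, n = 4 against 4), Il1a rose 134-fold and Ptgs2, the inducible cyclooxygenase, 81.6-fold. Tnf rose by 4.01 ± 0.0931, Il1b by 4.46 ± 0.263, Il12b by 5.11 ± 0.299, Ccl2 by 3.21 ± 0.238 and Nos2, which makes nitric oxide, by 3.6 ± 0.162. Adjusted p in limma with Benjamini-Hochberg adjustment was at most 5.33e-09 for these genes, and the groups did not overlap. RMA compresses changes of dim genes, and Il6 and Il1a averaged 4.24 and 5.47 without LPS, so their folds are not exact. Gcnt1, Rasgrp3, Cd28 and Hpgd, an enzyme that degrades prostaglandins, were among the largest falls, with log2 changes of -4.12, -4.19, -4.05 and -4.49. The gene lists moved as sets. All 20 measured members of the NF-kB list rose, also 20 adjusted over the list alone (camera adjusted p = 9.4e-21, and 0.013 with an estimated correlation). Of 22 cytokines 19 rose (19 adjusted over the list alone, adjusted p = 0.013 with an estimated correlation), and of 22 chemokines 18 rose and 2 fell (18 and 2, adjusted p = 0.013). Of 23 early response genes 18 rose and 1 fell (19 and 2, adjusted p = 0.0043 estimated), and of 13 nitric oxide, prostaglandin and itaconate enzymes 9 rose and 2 fell (9 and 2, adjusted p = 0.0088), including Ptges by 5.21.

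In the same cells 24 of 27 interferon genes rose (24 adjusted over the list alone, adjusted p = 7.9e-12, but adjusted p = 0.23 with an estimated correlation), with Usp18 up 3.11-fold and Gbp3 10.3-fold. Other calls were lost in the same way. Of 14 costimulation genes 9 rose (10 adjusted over the list alone, adjusted p = 0.061 with an estimated correlation), with Cd40 up by 4.07. Rises were called in 10 of 13 MHC class I genes (11 with 1 fall, adjusted p = 0.24), 16 of 22 glycolysis and HIF-1 targets with 2 falls (16 and 2, adjusted p = 0.28), with Slc2a1, a glucose transporter, up by 2.47, 13 of 22 Toll-like receptor genes with 4 falls (13 and 4, adjusted p = 0.27) and 4 of 16 stromal markers (4, adjusted p = 0.46). Falls were called in 13 of 31 cell cycle genes with 4 rises (14 and 4, adjusted p = 0.50), 6 of 12 MHC class II genes (6 with 1 rise, adjusted p = 0.26), with Ciita, their master regulator, at -2.39 ± 0.15, and 6 of 13 LXR targets with 1 rise (6 and 1, adjusted p = 0.16), with Abcg1, a cholesterol exporter, at -1.88. Mki67 was among the 4 cell cycle genes that rose, by 2.75, and Mcm7 among those that fell, by 1.39. In all, 2786 genes rose and 3346 fell, 697 and 930 of them at least 2-fold.

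LPS also raised inflammatory mediators in KO macrophages. Il6, which averaged 4.42 without LPS, so that its fold is again not exact, rose 84.5-fold (6.40 ± 0.136), Ptgs2 51.4-fold, Tnf 14.1-fold and Il1b 30.4-fold, while Nos2 rose only 2.47-fold (1.30 ± 0.162; adjusted p = 5.11e-06). Acod1, which makes itaconate, rose 31.9-fold. Cxcl10 rose by 5.52, Gbp5 by 5.02, Ifi205 by 5.66 and Saa3 by 4.62, and Slc40a1, the iron exporter, fell by 3.78. All 20 NF-kB genes rose (20 adjusted over the list alone, adjusted p = 0.0081 with an estimated correlation). Called members were 14 of 22 cytokines (14, adjusted p = 0.018), 16 of 22 chemokines with 2 down (16 and 2, adjusted p = 0.013), 16 of 23 early response genes with 4 down (16 and 4, adjusted p = 0.0088) and 8 of 13 nitric oxide, prostaglandin and itaconate enzymes with 1 down (8 and 1, adjusted p = 0.0081). All 27 interferon genes rose (27, adjusted p = 0.054 with an estimated correlation), and 14 of 16 cholesterol synthesis genes rose with 1 down (14 and 1, adjusted p = 0.12), among them Sqle, Cyp51 and Sc5d by 1.71, 1.63 and 1.30. MHC class I genes rose in 12 of 13 (12, adjusted p = 0.051), costimulation genes in 9 of 14 (9 with 1 fall, adjusted p = 0.062), Toll-like receptor genes in 11 of 22 with 2 falls (13 and 2, adjusted p = 0.061), glycolysis genes in 14 of 22 with 1 fall (17 and 3, adjusted p = 0.23) and oxidative phosphorylation genes in 8 of 23 (8, adjusted p = 0.39). Cell cycle genes fell in 14 of 31 with 2 rises (17 and 2, adjusted p = 0.40) and LXR targets in 4 of 13 with 1 rise (4 and 1, adjusted p = 0.17). The MHC class II list, with 3 of 12 up and 2 down (4 and 3), and the stromal list, with 2 of 16 up, were not called in KO cells (camera adjusted p = 0.85 and 0.20 at the preset correlation). For Ciita the change was -0.16 ± 0.15 (adjusted p = 0.542). In all, 2394 genes rose and 2525 fell, 670 and 584 of them at least 2-fold. Rises outnumbered falls with median centring (2743 and 2206), with the stricter filter on dim genes (2329 and 2168), on numbers 1 to 3 (2374 and 2343), and without KO unstimulated array 2 (2337 and 2208) or 3 (2274 and 2187) or KO LPS array 4 (2424 and 2270).

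**Figure D1:**
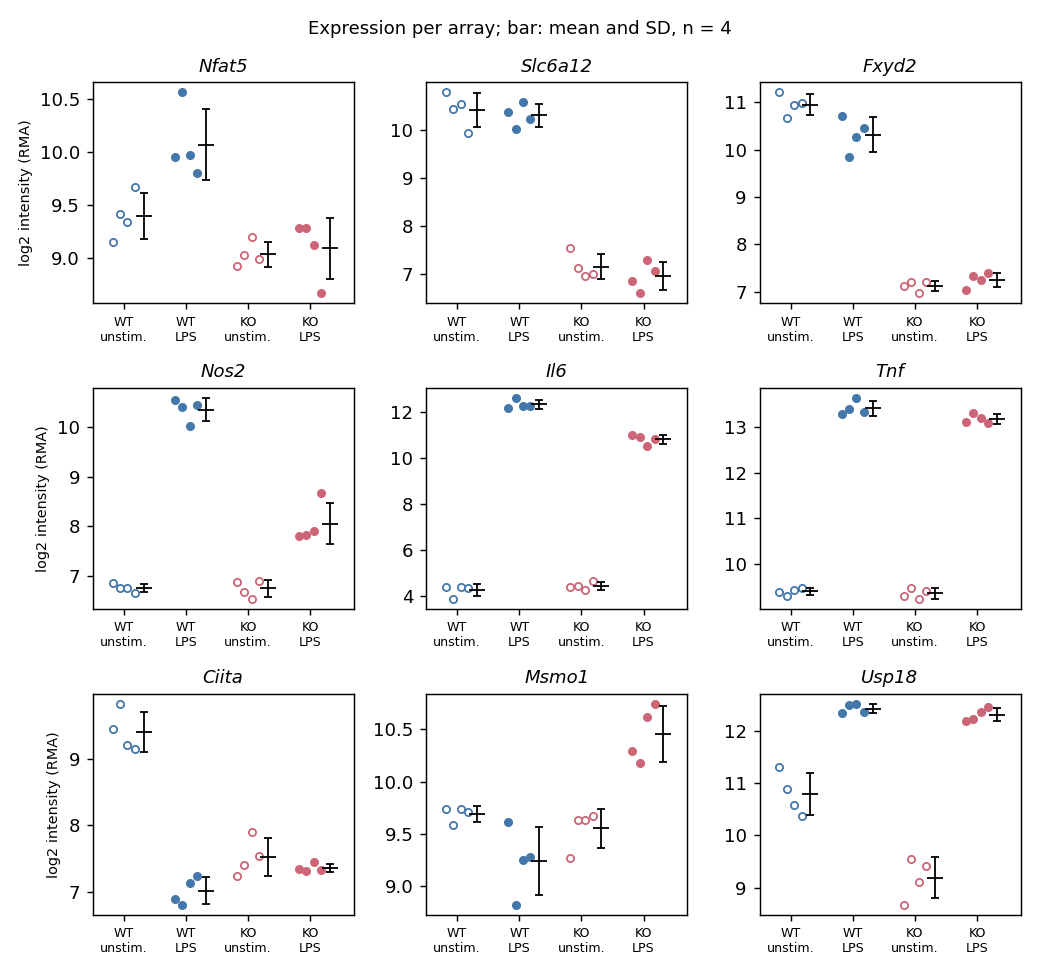
Log2 RMA expression of 9 genes in each array, by group, with open points for unstimulated and filled points for LPS-treated samples; bars give mean and SD (n = 4). Slc6a12 averaged 10.42 and 10.3 in wild-type cells without and with LPS and 7.16 and 6.96 in KO cells, and Nos2 under LPS was 10.35 in wild-type and 8.05 in KO cells on average.

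Without LPS, some genes of osmotic protection and of antigen presentation were lower in KO cells. Fxyd2, which encodes a subunit associated with the sodium pump and is not on the osmotic list, was 14.2-fold lower (-3.82 ± 0.152 on the log2 scale, adjusted p = 5.58e-11), and Slc6a12, the betaine transporter, was 9.58-fold lower (-3.26 ± 0.181, adjusted p = 8.59e-09). Slc5a3, the myo-inositol transporter, differed by -1.99 and Slc38a2, an amino acid transporter, by -2.05. Hpgd differed by -4.07 ± 0.522 but varied widely in KO cells (7.51 ± 1.7, SD). Of 12 osmotic stress genes 3 were lower (4 adjusted over the list alone, adjusted p = 0.0043 with an estimated correlation). The median log2 difference of the list was -0.0853 and the mean -0.657, so a few members carry its call. Of 12 MHC class II genes 6 were lower (6 lower and 1 higher adjusted over the list alone, adjusted p = 0.0054 with an estimated correlation), including H2-Aa at -2.28, H2-Eb1 at -2.04, H2-Ab1 at -1.81, Cd74 at -1.37 and Ciita at -1.88 ± 0.15.

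Interferon genes were lower too, in 14 of 27 (25 adjusted over the list alone, adjusted p = 3.4e-39, and 0.026 with an estimated correlation). Without wild-type array 1, 4 of the 27 were called. With all arrays Usp18 was 3.04-fold lower, Irf7 2.10-fold, Oasl1 1.98-fold and Ifih1 1.74-fold. Lower members were also called in 2 of 13 MHC class I genes (10, adjusted p = 0.04 with an estimated correlation), Tap1 at -0.92 and H2-M3 at -0.61, in 3 of 22 Toll-like receptor genes (7, adjusted p = 0.027), Cd14 at -1.20 and Tlr9 at -0.85, and in 3 of 13 nitric oxide, prostaglandin and itaconate enzymes (3, adjusted p = 0.027), Alox5 at -1.37, Acod1 at -1.14 and Pla2g4a at -1.02. For the NF-kB list, with 2 of 20 lower (5; Traf1 at -1.74), the call was lost with an estimated correlation, adjusted p = 0.062.
Sema4a, Slco4a1, Ifitm6 and Ms4a4c were also lower, with log2 differences of -2.26, -2.23, -2.18 and -2.1, and Slc40a1 (2.24), Dkk2 (1.25), Thbs1 (1.22) and Kitl (0.87) were higher. Nos2 (-0.01, adjusted p = 0.993), Il6 (0.18, 0.836) and Tnf (-0.04, 0.959) were not called. In all, 28 genes were higher and 172 lower in KO (limma with Benjamini-Hochberg adjustment), 3 and 65 of them at least 2-fold, and with the replicate number as a block 71 were higher and 256 lower. With that block the chemokine and lymphocyte lists were no longer called (adjusted p = 0.053 and 0.055) and the glycolysis list was (0.031). Without the block these 3 lists had adjusted p = 0.40, 0.44 and 0.62 with an estimated correlation, and 0 of 22, 0 of 13 and 0 of 22 members were called. Leaving out wild-type array 1, KO array 1 or wild-type array 2 left 128, 116 and 116 calls. Irf7 was not called without KO array 1 (adjusted p = 0.0559), Thbs1 without wild-type array 2 (0.0509) or KO array 3 (0.0622), and Tlr9 without wild-type array 1, KO array 1 or wild-type array 2 (0.0681, 0.07 and 0.0643). In the fit of only these 8 arrays Irf7, Ifih1, Oasl1, Tlr9 and Acod1 lost the call (adjusted p = 0.125, 0.0588, 0.0809, 0.109 and 0.12), and with the replicate block in that fit Irf7, Tlr9 and Acod1 did (0.103, 0.0816 and 0.0819). Without both arrays numbered 1, Irf7, Ifih1, Tlr9 and Acod1 lost it (0.071, 0.0713, 0.213 and 0.0673). In a fit of the 10 arrays with Xist above Kdm5d, where the 1 KO array per treatment is assumed to vary like the other groups, 58 genes were called (11 higher and 47 lower), and with a sex term in the full fit 359 (156 higher and 203 lower), of which 103 were among the 200. The sex term ended the calls of Ms4a4c, Irf7, Oasl1, Tlr9, Acod1, H2-M3 and Thbs1 (adjusted p = 0.0532 to 0.112). With the block added to it Ifitm6, Ms4a4c, Usp18, Irf7, Ifih1, Oasl1, Tlr9, Acod1, Tap1, H2-M3, Dkk2 and Thbs1 were not called (0.0836 to 0.413), and in the 10 arrays neither were these 12 nor Pla2g4a and Slc40a1 (0.0504 to 0.439). The log2 differences of these 14 genes in the 10 arrays stood at a median of 87.2% of those in the full fit (57% to 125%), and that fit has fewer samples. For the genes that lost the call with the sex term, and with the block beside it, the medians were 82.6% and 69.5%.

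**Figure D2:**
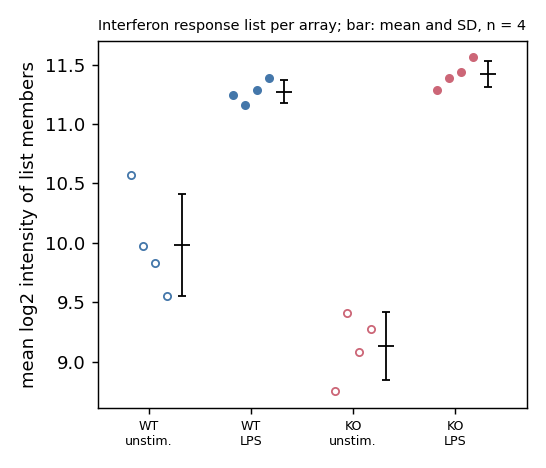
Mean log2 RMA expression of the 27 measured interferon response genes in each array, with mean and SD (n = 4) per group. Unstimulated wild-type arrays ranged from 9.56 to 10.57, KO arrays from 8.75 to 9.41, and LPS arrays of both genotypes lay between 11.2 and 11.6.

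With LPS, cytokines and chemokines that the stimulus induces were lower in KO cells, and cholesterol synthesis genes were higher. Nos2 was 4.93-fold lower (-2.30 ± 0.162, adjusted p = 2.2e-07), Il6 2.88-fold lower (-1.53 ± 0.136, adjusted p = 4.54e-06) and Serpinb2 6.04-fold lower (-2.59 ± 0.268, adjusted p = 2.16e-05). Among KO arrays with LPS, Nos2 was highest in number 4 (8.669, against at most 7.909 in the others), the only one without Y-linked transcripts. Trem1, which amplifies inflammatory signalling, differed by -2.46, Lcn2 by -1.91 and Olr1 by -2.13, and Slc6a12 and Fxyd2 by -3.34 and -3.07. Of 22 cytokines 9 were lower (13 lower and 1 higher adjusted over the list alone, adjusted p = 0.02 with an estimated correlation), among them Il1a at -1.68, Csf3 at -1.41, Il12b at -1.35 and Osm at -1.24. Tnf (-0.23, adjusted p = 0.294) and Il1b (-0.42, adjusted p = 0.683) were not called. In the fit of only these 8 arrays, where its groups did not overlap, Il1b was called (adjusted p = 0.0253, and 0.0157 with the replicate block in that fit). Of 22 chemokines 8 were lower (11, adjusted p = 0.02 estimated), including Cxcl1 at -1.15, Cx3cl1 at -1.19, Ccl7 at -1.28, Ccl2 at -1.12 and Ccl4 at -0.68. Of 23 early response genes 11 were lower (14 lower and 1 higher, adjusted p = 0.0024), such as Nr4a1 at -1.19, Ier3 at -1.17, Egr2 at -0.85 and Egr1 at -0.82, and of 13 nitric oxide, prostaglandin and itaconate enzymes 6 were lower (7 lower and 1 higher, adjusted p = 0.0043), including Ptges at -1.23, Slc7a2 at -1.44, Pla2g4a at -1.05 and Ptgs2 at -0.56.

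Of 16 cholesterol synthesis genes 9 were higher (14 adjusted over the list alone, adjusted p = 0.02 with an estimated correlation), with Msmo1 at 1.21, Fdft1 at 1.01, Fdps at 0.84 and Sqle at 0.82. Kcnj10 (2.05), Apol7c (2.77), Plxna2 (1.68), Gpr162 (1.48) and Sesn1 (1.40) were also higher. The interferon list held 0 called members of 27 (median log2 difference 0.08; adjusted p = 0.037, but adjusted p = 0.72 with an estimated correlation), and the call was lost with the replicate block (adjusted p = 0.058). The MHC class II list, with 4 lower and 1 higher of 12 (4 and 1, adjusted p = 0.36 with an estimated correlation), lost it with the block too (0.061). Among its members H2-Aa was at -1.41 and H2-Eb1 at -1.45, and for Ciita the difference was 0.34 ± 0.15 (adjusted p = 0.363). The osmotic list, with 3 of 12 lower (3 lower and 1 higher), and the NF-kB list, with 3 of 20 lower (6), had adjusted p = 0.11 and 0.17 with an estimated correlation.

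In all, 358 genes were higher and 251 lower in KO (limma with Benjamini-Hochberg adjustment), 31 and 85 of them at least 2-fold, and with the replicate block 569 were higher and 381 lower. The block added calls for the LXR, dendritic cell and sex-linked lists (adjusted p = 0.014, 0.031 and 0.034). Without the block their adjusted p with an estimated correlation was 0.19, 0.40 and 0.15. Without wild-type array 2, 308 genes were called, and without KO array 1, 394. Calls lost by leaving out 1 array were Ccl2 (KO 1, adjusted p = 0.052; wild type 2, 0.0587), Il12b (wild type 2, 0.077; KO 3, 0.0646; KO 4, 0.0506), Slc5a3 (wild type 2, 0.0534; -0.82 with all arrays), Sqle (wild type 2, 0.0639; KO 3, 0.0504), Ptgs2 (wild type 2 and 3, KO 3 and 4, 0.0668 to 0.104), Slc38a2 (wild type 1 to 3, KO 3 and 4, 0.054 to 0.0888; -0.93 with all), Tnip1 (wild type 1 and 2, KO 2 and 3, 0.0513 to 0.0736; -0.38 with all) and Tnfaip3 (any of the 8 arrays, 0.071 to 0.163; -0.54 with all). In the fit of only the 8 arrays Il12b, Ccl7, Fdps and Slc38a2 lost the call (adjusted p = 0.0594, 0.0688, 0.0814 and 0.0853), and with the replicate block in that fit Ccl7 and Ccl2 did (0.0728 and 0.0553). Median centring ended those of Tnfaip3 and Tnip1 (0.0613 and 0.0561), and numbers 1 to 3 alone those of Fdps, Sqle, Slc5a3 and Tnfaip3 (0.0618 to 0.107). In the arrays with Xist above Kdm5d 89 genes were called (32 higher and 57 lower), where Ccl2 was at -0.40 (adjusted p = 0.536) and Ccl7 at -0.37 (0.548), and with a sex term 671 (337 higher and 334 lower), of which 342 were among the 609. With that term Ccl2 was at -0.63 (adjusted p = 0.194) and Ccl7 at -0.82 (0.134), and Ier3, Ptgs2, Tnfaip3 and Tnip1 were not called (0.052 to 0.208). The block beside it also ended the calls of Csf3, Il1a, Il12b, Ccl4, Cx3cl1, Ptges, Fdft1, Fdps, Plxna2, H2-Aa and Slc5a3 (0.0544 to 0.238). Further genes not called in the arrays with Xist above Kdm5d were Trem1, Cxcl13, Lcn2, Osm, Csf3, Il12b, Ccl4, Cx3cl1, Nr4a1, Egr1, Egr2, Ier3, Ptges, Ptgs2, Fdft1, Fdps, Plxna2, H2-Aa, H2-Eb1, Traf1, Tnfaip3 and Tnip1 (0.0509 to 0.408). Over all 30 named genes that lost the call there, the log2 difference was at a median of 97.9% of that in the full fit (29.3% to 148%), and 14 were at least as large. With the sex term, and with the block beside it, the medians were 72.5% and 79.7%, with 1 of 8 and 5 of 21 at least as large.

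Genes called for genotype under LPS were over-represented among LPS-responsive genes, although 305 of the 609 lay outside them. Of 675 genes induced at least 2-fold by LPS, 126 (18.7%) were lower in KO under LPS and 9 were higher. Of 733 repressed genes 166 (22.6%) were higher and 3 lower, and of 18529 other genes 122 were lower and 183 higher. The odds ratio against the other genes was 34.6 for lower among induced and 29.4 for higher among repressed genes. The other genes include dim ones, whose changes RMA compresses, and both calls use the same estimate of each gene's spread. The ratios may therefore overstate the link. Without wild-type LPS array 2 the share of induced genes was 10.6%, and in the arrays with Xist above Kdm5d, with 1 KO array per treatment, it was 3.25%. With a sex term in the full fit it was 17.3%, and with the block beside that term 6.37%. The slope of the genotype difference in response on the average response was -0.089 for induced genes (SD 0.1 over the 4 replicate numbers) and -0.0797 (SD 0.028) for repressed genes. The median response of induced genes was 1.57 in wild-type and 1.52 in KO cells, with 34 called more positive in KO and 38 more negative. For repressed genes the medians were -1.53 and -1.2, with 69 more positive and 2 more negative.

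**Figure D3:**
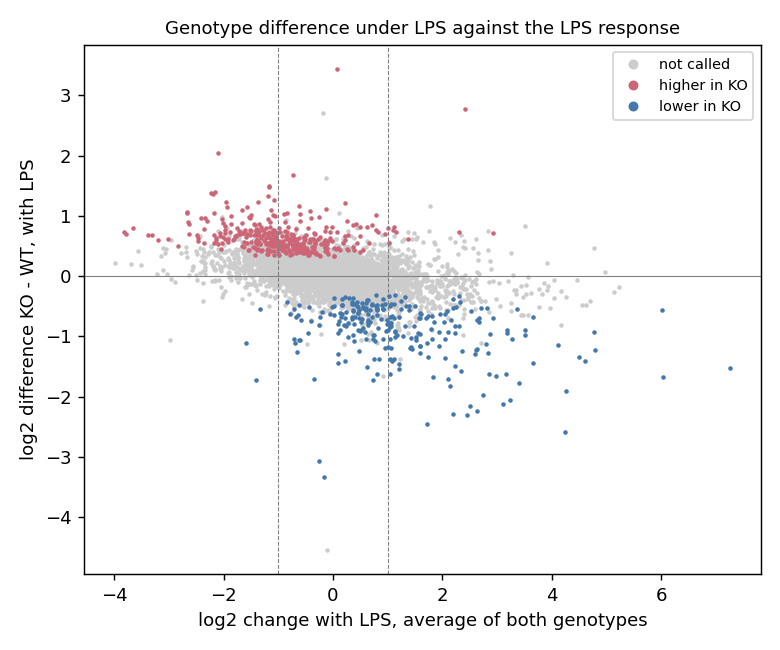
Each point is a gene, with its log2 change with LPS averaged over both genotypes on the horizontal axis and the log2 KO minus wild-type difference under LPS on the vertical axis. Dashed lines mark 2-fold changes. Genes lower in KO (251) and higher in KO (358) at adjusted p under 0.05 are coloured.

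The response to LPS itself differed between genotypes for 257 genes, 197 with a more positive and 60 with a more negative change in KO. Nos2 (-2.29 ± 0.23, adjusted p = 7.35e-05), Il6 (-1.71 ± 0.192), Serpinb2 (-2.58), Trem1 (-2.43), Upp1 (-2.20), Il1a (-2.07), Olr1 (-2.00) and Tmc3 (-1.76) had the more negative change. Tnf (-0.19, adjusted p = 0.731) and Ptgs2 (-0.67, adjusted p = 0.101) were not called, and Ptgs2 was called without KO unstimulated array 1 (0.0299), with array weights (0.0174) and without both unstimulated arrays numbered 1 (0.0405). Of 23 early response genes 3 were more negative and 1 more positive (7 and 2 adjusted over the list alone, adjusted p = 0.013 with an estimated correlation). Of 22 cytokines 6 were more negative (9 more negative and 1 more positive, adjusted p = 0.14). Ciita (2.22 ± 0.212), Kcnj10 (1.80) and Apol7c (2.54) had the more positive change. Cholesterol synthesis genes, with Msmo1 at 1.35 and Fdft1 at 1.43, were more positive in 5 of 16 (12, adjusted p = 0.02), and MHC class II genes, with H2-DMa at 1.49, in 2 of 12 (4, adjusted p = 0.034).

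The interferon list had 8 of 27 more positive members (23 adjusted over the list alone, adjusted p = 0.061 with an estimated correlation), Ifit2 at 2.12, Ifit3 at 1.96, Ifit1 at 1.70 and Mx1 at 1.67 among them, and Tnfsf10 had 1.72, Tlr9 1.25 and Tap1 0.98. MHC class I genes were more positive in 2 of 13 (6, adjusted p = 0.12). Some calls on the difference in response were lost by leaving out 1 array. This held for Ifit1 with KO unstimulated 1 or 3, wild-type unstimulated 2, wild-type LPS 1 or 2, or KO LPS 1, 3 or 4 (adjusted p = 0.0526 to 0.0727), and for Ifit2 with the same arrays except KO LPS 1 (0.055 to 0.0752). It held for Mx1 with wild-type unstimulated 1, 2 or 3, wild-type LPS 1 or 2, or KO LPS 3 or 4 (0.0574 to 0.0787), and for H2-DMa without wild-type unstimulated array 2, wild-type LPS array 2 or KO LPS array 3 (0.0586 to 0.0611). Without KO unstimulated array 1, wild-type unstimulated array 2, wild-type LPS array 2 or KO LPS array 1, 2 or 3, the genes called numbered 149, 136, 133, 148, 168 and 145. With the replicate block 451 genes were called, and 4 in the arrays with Xist above Kdm5d, where Nos2, Il6, Serpinb2, Trem1, Upp1, Il1a, Ciita, Kcnj10, Apol7c, Ifit1, Ifit2, Ifit3, Mx1, Tnfsf10, H2-DMa, Tap1, Msmo1, Fdft1 and Tlr9 lost the call (adjusted p = 0.0695 to 0.602). The differences of these 19 genes stayed at a median of 96% of those in the full fit (56.6% to 112%), and that fit has 1 KO array per treatment. A sex difference of equal size with and without LPS cancels in this contrast, because both KO groups held the same mix of sexes. With the sex term, which removes only such a difference, 320 genes were called, all 257 among them. Whether the response to LPS depends on sex was not tested. Cyclic loess ended the calls of Ifit1 and Mx1 (0.0504 and 0.0522) and a trended robust variance that of Ifit2 (0.066). Numbers 1 to 3 alone ended those of Il1a, H2-DMa and Fdft1 (0.0571, 0.0821 and 0.052), and leaving out both unstimulated arrays numbered 1 those of Apol7c, Ifit1, Mx1, H2-DMa and Fdft1 (0.0517 to 0.0706).

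Of the 172 genes lower in KO without LPS and the 251 with LPS, 33 were shared, against 2.17 for independent lists, among them Fxyd2, Slc6a12, Cxcl13 (-2.05 with LPS), Pla2g4a and Traf1. Of the 28 and 358 higher genes 6 were shared, against 0.503. The expected counts run over all genes tested, dim ones included, and both contrasts use the same estimate of each gene's spread. Both also set mostly male KO arrays against female wild-type arrays. The excess may therefore overstate a shared genotype effect. Across genes, which are not independent replicates, the 2 differences correlated with Pearson's r = 0.192 and Spearman's rho = 0.00125.

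The other lists were as follows. Alternative activation, the unfolded protein response, osteoclast, mast cell, erythroid and dendritic cell markers were called in no contrast at the preset correlation (adjusted p from 0.057 to 0.95). Calls not held with an estimated correlation included cell cycle genes without LPS (0 of 31 called; adjusted p = 0.26), cholesterol synthesis without LPS (0 of 16; adjusted p = 0.39), macrophage identity with LPS (1 of 21 higher; adjusted p = 0.21) and in the response (adjusted p = 0.093), oxidative phosphorylation (0 of 23 with LPS; adjusted p = 0.28), neutrophil markers in the response (1 of 16 more negative; adjusted p = 0.39), lysosome genes in the response (0 of 16; adjusted p = 0.41), NRF2 targets with LPS in KO cells (5 of 14 up and 2 down; adjusted p = 0.44), lymphocyte markers (0 of 13 without LPS; adjusted p = 0.44), and sex-linked genes without LPS (0 of 4 over all genes and 3 higher with 1 lower adjusted over the list alone, adjusted p = 0.072).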

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

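The tests of sex on the genotype differences and of a weaker response of all induced genes were chosen only after the result was seen, as was the demand for more than 1 KO array before sex is excluded.

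Among 396 gene and group combinations, 12 had 1 array far from the others by Dixon's gap ratio, where chance gives about 1 in 20. In unstimulated KO cells these were Cd28 (0.913, array 4 high), H2-DMa (0.955, array 1 low) and Msmo1 (0.898, array 1 low), and in unstimulated wild-type cells Il6 (0.853, array 2 low) and Tnfsf10 (0.875, array 1 high). With LPS they were Kitl (0.869, array 3 low), Nos2 (0.877, array 4 high) and Slc2a1 (0.897, array 4 low) in KO cells, and Slc38a2 (0.931, array 4 low), Sqle (0.836, array 2 low), Tnfaip3 (0.836, array 2 high) and Tnfsf10 (0.914, array 2 low) in wild-type cells.

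The response to LPS of 42 named genes differed between genotypes by the test of the difference itself. The log2 change was more negative in KO for Serpinb2 (-2.58), Trem1 (-2.43), Nos2 (-2.29), Upp1 (-2.20), Il1a (-2.07), Olr1 (-2.00), Lcn2 (-1.89), Tmc3 (-1.76), Il6 (-1.71), Slc40a1 (-1.64), Csf3 (-1.43), Slc7a11 (-1.42), Nr4a1 (-1.41), Adm (-1.28), Egr1 (-1.27), Ier3 (-1.24), Osm (-1.21) and Cxcl1 (-0.88). It was more positive for Apol7c (2.54), Ciita (2.22), Ifit2 (2.12), Ifit3 (1.96), Kcnj10 (1.80), Tnfsf10 (1.72), Ifit1 (1.70), Mx1 (1.67), H2-DMa (1.49), Usp18 (1.49), Fdft1 (1.43), Sesn1 (1.42), Msmo1 (1.35), Slco4a1 (1.28), Tlr9 (1.25), Sema4a (1.20), Sqle (1.18), Slc5a3 (1.17), Alox5 (1.12), Cd14 (0.99), Tap1 (0.98), Gpr162 (0.90), Ifih1 (0.88) and H2-M3 (0.69).

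Probe sets without a single gene carried signal outside the gene comparisons: of 13120, 1406 were called for LPS in wild-type cells, 1152 for LPS in KO cells, 7 and 41 for genotype without and with LPS, and 5 for the difference in response.

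The genotype differences go with sex, since 6 of 8 KO arrays carry Y-linked transcripts and no wild-type array does. Between the arrays numbered 4, which carry none in either genotype, autosomal genes called on numbers 1 to 3 kept a median signed difference of 0.549 without LPS and 0.494 with LPS, where the largest between wild-type arrays was 0.495 and 0.349. The excess over that bound was 0.0542 and 0.145, where the SD between wild-type pairs was 0.146 and 0.12. Each value rests on 1 KO array, so sex and genotype cannot be told apart for these genes as a set. Some single genes held their size in all 25 settings, those for sex included. Without LPS this held for Fxyd2 (-3.919 to -3.712) and Slc6a12 (-3.421 to -3.008), and with LPS for Il6 (-1.589 to -1.399). Others varied more with LPS, such as Nos2 (-2.509 to -1.684) and Ccl7 (-1.706 to -0.3741). Lower genes went from a median of -1.05 on numbers 1 to 3 to -0.583 in number 4 without LPS, and from -0.829 to -0.639 with LPS. Higher genes went from 0.722 to 0.244 and from 0.656 to 0.435. The direction was kept by 95.5% and 92.6% of lower genes and by 78.3% and 94.7% of higher genes. Choosing the genes on numbers 1 to 3 favours larger values there, and sex could account for part of the drop too. The genotype effect remains a hypothesis.

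Interferon genes were lower in unstimulated KO cells, where wild-type array 1 had the highest list mean (10.57) and KO array 1 the lowest (8.754). Without wild-type array 1 the median member difference was -0.651 and camera with an estimated correlation gave p = 0.0049. This argues against that array as the sole cause, though called members went from 14 to 4 of 27. The test kept KO array 1, so it does not address both arrays numbered 1 together. In numbers 2 to 4 the list means were 9.978, 9.835 and 9.555 in wild-type and 9.413, 9.082 and 9.28 in KO arrays. In number 4 the median was -0.262, within the -1.06 seen between wild-type arrays, and 1 KO array cannot decide, so sex and genotype cannot be told apart for this list.

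LPS-induced genes were lower in KO under LPS, with a median difference of -0.211. A weaker response of all induced genes was tested on the 23 induced interferon genes, whose median was 0.0827 with a lower quartile of -0.0604. That test cannot decide, because it used levels under LPS and the interferon list already had a median difference of -0.841 without LPS. In the response itself, 34 of 675 induced genes were called more positive in KO and 38 more negative. These counts argue only against a smaller log2 change in every induced gene. A gene that starts lower in KO can change more without reaching a higher level. Of the 172 genes lower in KO without LPS, 63 were called for the difference in response. The counts therefore do not show that levels under LPS were spared. For sex, a bound set before the result was passed, -0.157 in number 4 against -0.149 between wild-type arrays, but that bound was wrong as an exclusion because it rests on 1 KO array and the excess is small, so sex and genotype cannot be told apart. A genotype effect on part of the induced genes is a candidate explanation.

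Other splits of the arrays were counted for each result. Over all splits chance is excluded for the genes called with LPS in wild-type (6132 real, at most 1 in the other of 35 splits) and KO cells (4919 and 4), for genotype without LPS (200 and 1) and with LPS (609 and 2), for the share of induced genes (18.67% and 0.2963%), for the lists called for genotype with LPS (17 and 13 when adjusted within the contrast) and, over 100 drawn splits, for the difference in response (257 and 67). In each of these 1 split, the real one, was as large. The draws for the difference in response took no account of the replicate numbers, which pair the arrays by genotype. The 8 splits that part as many pairs are too few for a share under 0.05. Among them the others called 0 genes for either genotype contrast and gave a share of 0%, but up to 13 lists with LPS against 17, and without LPS 3 of the 8, the real one included, were as large (up to 15 lists against 10). Chance is not excluded for lists called in wild-type LPS (7 of 35 splits as large; 14 real and 15 highest other), KO LPS (3 of 35; 15 and 17), genotype without LPS (6 of 35; 10 and 15) and the response (6 of 100; 14 and 17). Every other split as large in the first 3 (6, 2 and 5 splits) exchanged 1 array per group and so kept part of the real contrast, and splits that exchanged 2 gave at most 11, 5 and 8 lists, so list counts separate such splits poorly. Nor is it for the slopes (31 of 100 with sizes 0.08899 and 0.1689 for induced genes, 6 of 100 with 0.07971 and 0.08833 for repressed genes) or the correlation between genotype differences (34 of 100; 0.1924 and 0.4816).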

How the results depend on the processing

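Fits with a sex term, with arrays chosen by Xist, with numbers 1 to 3 only, with 8 arrays and a block, or without both unstimulated arrays numbered 1 were chosen only after the data were seen. For named genes, 4001 alternative values kept the call or its absence (12 of them, of 3 uncalled differences, with the other sign), 225 lost the call, 5 gained one (Il1b with LPS in 2 settings and the Ptgs2 response in 3) and 0 reversed. For lists the numbers were 4158, 190, 110 and 7. No scaling moved the share of higher calls by over 10 points, though centring made rises the larger part for LPS in KO cells (55.4%). For the LPS contrasts, where numbers pair less clearly (correlations from 0.045 in wild-type and from -0.06 in KO cells, with 6 of 8 and 4 of 8 arrays closest to their own number), the replicate block gave 6874 and 5624 calls.

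The replicate block gave 327 calls for genotype without LPS, 950 with LPS and 451 for the difference in response, and kept all 200, 609 and 257. A random block gave 412 for the last. Array weights gave 1419 with LPS, 492 for the response and a share of induced genes of 28.5%. The weights were 0.373 to 0.557 for arrays numbered 4, and 0.505 and 0.397 for the unstimulated wild-type and KO arrays numbered 1. All others had 0.998 or more. Number 4 alone has KO and wild-type arrays of the same sex, so these weights favour comparisons between the sexes. Without weights the share was 29.1% for genes induced at least 4-fold. Camera with an estimated correlation called 24 lists. Only the groups of the contrast gave 91 without LPS, and 8 arrays with the block 1149 with LPS. Across genes called in either state the genotype differences correlated by 0.341. For Nfat5 without LPS the difference was -0.299 with cyclic loess and -0.391 with centring, both with exact permutation p = 0.0286. The causes were not tested.

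A sex term gave 359 without LPS, and with the block 84 without LPS, 142 with LPS (59 higher and 83 lower), 469 for the response and a share of 6.37%. Without the block that term also carries any difference of KO number 4 from KO numbers 1 to 3 that is not due to sex. The direction of the list test turned, with the median given here, with the sex term for chemokines without LPS (-0.0512), and with the block added for chemokines (0.188), costimulation (0.35), NRF2 targets (-0.194) and sex-linked genes (0.011) without LPS, and costimulation (0.0962) and NRF2 targets (-0.212) with LPS. Calls were lost with the sex term as the median changed sign for sex-linked genes without LPS (-0.00278) and MHC class II with LPS (0.000664). Arrays with Xist above Kdm5d gave 1962 for LPS in KO cells, 58, 89, 4 and 3.25% in the order above; having 1 KO array per treatment, this fit has fewer samples. Numbers 1 to 3 gave 153 for the response, and leaving out both unstimulated arrays numbered 1 gave 80 without LPS and 108 for the response.

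Leaving out 1 array at a time gave 5432 to 6016 calls for LPS in wild-type cells, 4408 to 4769 in KO cells, 116 to 209 for genotype without LPS, 308 to 606 with LPS, 133 to 271 for the response, a share of 10.6% to 20.3%, slopes of -0.111 to -0.0667 for induced and -0.0946 to -0.0533 for repressed genes, and 59 to 75 lists. The difference in response was not run on only its groups, which are all 16 arrays. Dim genes have compressed changes in RMA values, so absence of a call there says little.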

Other observations

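With LPS, further genes differed in KO cells outside the lists led with above. Adm, a hypoxia-inducible peptide, differed by -1.35 and Hif1a by -0.50, Slc7a11, the cystine transporter, by -1.41 and Fn1, the matrix protein fibronectin, by -1.72. Abcg1, a cholesterol exporter, differed by 0.77, Scd2, a fatty acid desaturase, by 1.5 and Mertk, a receptor for dying cells, by 0.79. Of 22 glycolysis and HIF-1 targets 2 were lower (6 adjusted over the list alone; adjusted p = 0.32 with an estimated correlation), and of 13 LXR targets 3 were higher (3 higher and 2 lower; adjusted p = 0.19). Calls were lost on leaving out 1 array for Abcg1 (KO 1, adjusted p = 0.0597), Hif1a (wild type 1 and 2, KO 1 to 4, 0.0542 to 0.16) and Scd2 (wild type 1 to 3, KO 1, 3 and 4, 0.0635 to 0.169), and in the fit of only these 8 arrays for Abcg1, Hif1a and Scd2 (0.0666, 0.0805 and 0.0517), all in limma with Benjamini-Hochberg adjustment. The replicate block in that fit ended the call of Abcg1 (adjusted p = 0.0599), a trended robust variance and numbers 1 to 3 alone that of Scd2 (0.0848 and 0.0979), and a sex term those of Abcg1 and Mertk (0.171 and 0.0915). With the block beside the sex term Abcg1, Adm, Mertk and Hif1a were not called (0.0544 to 0.509), and in the arrays with Xist above Kdm5d neither were these nor Scd2 (0.0504 to 0.465).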
